A study of Homo sapiens with 6 samples.

How the data were processed

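Libraries of polyadenylated RNA, made with a stranded kit, came from UTA-SF2-2 cells, a human iPS cell line, under induction to endothelial cells. The series has 2 libraries at each of days 11, 14 and 24, and all 6 were used. The labels number the libraries of a day 1 and 2 and do not say whether they come from separate cultures. They name no sorting step, no batch and no pairing across days. The 3 days were the groups, and no sample was left out.

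The authors deposited 1 table of FPKM values for 26255 gene symbols, with 1 column per library. FPKM here is normalised by the authors for transcript length and library size, and the values are not counts. The unit was taken from the name of the table and tested on the values, which were non-whole, at least 0 and summed to 390295 to 515033 per library, so they had not been rescaled to a common total. Per the submitters' processing notes, featureCounts 2.0.0 and the genome build hg19 were used. The aligner, the annotation and the strand setting are not given in the sources used here. The table holds no transcripts encoded by the mitochondrial genome, so the list of these fixed beforehand could not be tested. It lists 7247 genes at 0 in all 6 libraries. Some of these can be failed estimates, and an exact 0 is reported only as "listed at 0".

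The depth was estimated from the values, since FPKM carries no counts. Low values of genes with 1 annotated transcript of over 600 bases stand at multiples of the value of 1 fragment, which put the 6 libraries at 8500000, 8900000, 7800000, 9300000, 9800000 and 8100000 fragments in the order of the days. These figures rest on the transcript lengths of a newer annotation and served no other purpose than to judge precision. Differences between the libraries of a day were larger than counting error. This was judged on genes with 1 such transcript and FPKM of at least 20, of which there were 130, 131 and 135 at days 11, 14 and 24. Over them the median chi-square was 9.52, 7.06 and 6.52 times that of counting error alone. No nonzero value was identical in both libraries of a day. The 50 most abundant genes took 15.8% to 22.4% of the sum of FPKM.

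Genes with FPKM of at least 1 in at least 2 of the 6 libraries were tested, 12861 in all. Values were transformed to log2(FPKM + 1). limma 3.58.1 in R 4.3.3 fitted 1 mean per day to all 6 libraries, followed by 3 contrasts and empirical Bayes moderation with a trend on mean expression (3 residual and 4.43 prior degrees of freedom). P-values were two-sided, adjusted by Benjamini-Hochberg over the genes of a contrast, with a threshold of 0.05. Because the libraries of day 14 enter both steps, the calls of consecutive steps are not independent. A moderated F test over the 3 days was adjusted the same way. Fold changes are differences of means of log2(FPKM + 1), and a change of at least 2-fold is a difference of at least 1 on that scale. The ratio given for BST1 is of mean FPKM.

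Lists of genes for endothelial subtypes, other cell types and processes were fixed by hand, 43 in all, of which 39 had at least 5 tested members. They were tested with limma camera with the inter-gene correlation preset to 0.01 and again with the correlation estimated from the data for each list, adjusted over the lists of a contrast. With an estimated correlation camera also uses only the 3 residual degrees of freedom, which makes it a far stricter test whatever the correlation. Camera compares a list with all other tested genes. Several lists share genes, so their results are not independent. For 4 list genes the table has an older symbol, which was used.

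The comparisons, tests, lists and alternatives and the rule for naming genes were chosen before the data were examined. By that rule the text names, for each contrast, the 10 largest rises and the 10 largest falls among genes past the threshold, with mean FPKM of at least 5 at 1 of the days and both libraries of 1 day above both of the other. Genes of the Y chromosome, XIST, TSIX and identifiers without a gene symbol were left out. From each list it allows up to 4 members past the threshold with the largest change, and for lists with none up to 3 members by value. BST1, PECAM1, CDH5, KDR and VWF were always named. Not every gene that the rule allows is named. Genes named outside the rule are marked as chosen after their values were seen.

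The method was tested on simulated data with the spread of these genes and no change except where added. For day 14 against day 11, it recovered 42% of 50 genes changed by 0.5 on the log2 scale, 88% at 1, 98% at 2 and 100% at 3. These genes, and those of the shifted list below, were drawn from genes with mean log2(FPKM + 1) of at least 2. The rates therefore do not cover tested genes of lower expression. The method called 5 unchanged genes, and 0 of 40 random lists. Genes were simulated independently of each other, so the random lists do not measure false calls among correlated members. In the data the estimated correlation reached 0.527 in the cell cycle list. A list of 20 genes shifted by 0.7 had adjusted p = 1.2e-34 with the preset correlation and adjusted p = 0.0341 with the estimated one. Few genes changed in the simulated data, so these values do not give the power of the list test in the real comparisons, where most genes changed.

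Alternatives were a pseudocount of 0.1 or 5, no filter on low values (19008 genes above 0), a filter at mean FPKM of at least 5, FPKM rescaled to a common total per library (the TPM scale), quantile normalization, moderation without the trend, a fit on the 4 libraries of the days compared, the replicate number as a block, and each library left out in turn. For lists the estimated correlation was a further alternative. The name tables used, GENCODE v29 and RefSeq, are on a newer build than hg19. They served for gene names (22942 of the symbols), neighbours and transcript lengths, and no coordinates are given. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.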

Results

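RNA was sequenced from cells of UTA-SF2-2, a human induced pluripotent stem (iPS) cell line, while they were induced to endothelial cells with a commercial differentiation kit. Libraries were made from polyadenylated RNA at days 11, 14 and 24 of the induction, with 2 libraries per day and 6 in all. The series title is about endothelial cells that carry CD157, the surface protein encoded by BST1, so BST1 was followed at each day. The labels name no sorting step, no batch and no separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical. Expression is given as FPKM (fragments per kilobase of transcript, scaled to the size of the library), which carries no counts. The steps between low values put the depth at 7800000 to 9800000 fragments per library, an estimate only. The sum of FPKM was 390295 and 392808 at day 11, 399822 and 407160 at day 14, and 499907 and 515033 at day 24. Unless stated otherwise, values are mean FPKM ± SD of the 2 libraries of a day, and fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

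The transcriptome differed between the 3 days by far more than between libraries of 1 day. Pearson's r over the 12861 tested genes, which are not independent replicates, was 0.987 to 0.992 between libraries of the same day and 0.789 to 0.884 between days. Days 11 and 24 were the least alike. The first principal component held 67.6% of the variance and ordered the libraries by day, and the next held 27.3% and separated day 14 from both other days. In the moderated F test of limma, 10490 of the 12861 genes changed over the 3 days, and 4542 of them had a range of at least 2-fold between days. The most frequent order among the 10490 was highest at day 24 and lowest at day 11, with 3232 genes. The opposite order held for 2832 genes. These orders were counted on the deposited scale only. With each library rescaled to a common total, 3223 genes were higher and 6360 lower at day 24 than at day 11, so which order is more frequent may depend on scaling. Day 14 was the highest day for 1256 genes that were lowest at day 24 and for 957 genes that were lowest at day 11. It was the lowest day for 1231 genes that were highest at day 24 and for 982 that were highest at day 11.

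**Figure D1:**
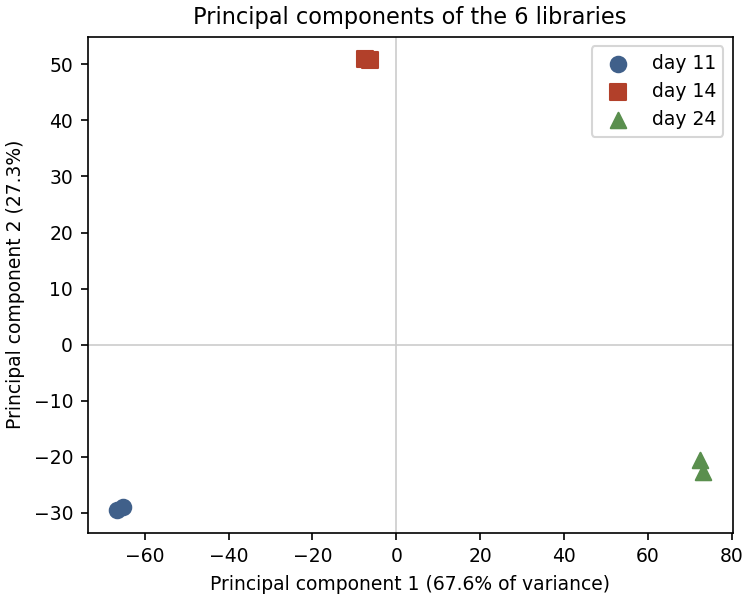
Each point is 1 library placed by its first and second principal component of log2(FPKM + 1), with the share of variance on each axis and the marker giving the day. The first component runs from -66.6 at day 11 to 73.2 at day 24, and only the day 14 libraries lie above 0 on the second, at 50.8 and 50.9.

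BST1 was 23.1 times as abundant at day 14 as at day 11 and fell back by day 24. Its FPKM was 13.6 and 16.3 at day 11, 371 and 321 at day 14, and 17.6 and 16.4 at day 24. The log2 fold change was 4.44 from day 11 to day 14 (SE 0.11, limma adjusted p = 1.78e-07) and -4.26 from day 14 to day 24 (SE 0.11, adjusted p = 2.18e-07). From day 11 to day 24 it was 0.18 (95% interval -0.07 to 0.43, adjusted p = 0.161). Without day 11 replicate 2 the last difference was 0.30 and passed the threshold (adjusted p = 0.0462). The endothelial genes PECAM1, CDH5, KDR and VWF followed other courses. PECAM1, an adhesion molecule of endothelial junctions, was at 87.1 ± 1.07, 78.9 ± 7.24 and 134 ± 0.22 at days 11, 14 and 24, and its rise from day 14 to day 24 passed the test (adjusted p = 8.56e-05). CDH5, which encodes VE-cadherin, was at 717 ± 2.02 and 664 ± 8.72 and fell to 502 ± 14.4 (adjusted p = 0.000679). Its step from day 11 to day 14 did not pass on the deposited scale. That step passed after rescaling to a common total (log2 fold change -0.15, adjusted p = 0.0374) and after quantile normalization (log2 fold change -0.37, adjusted p = 0.00101). KDR, the main receptor for VEGF-A, fell from 874 ± 47.8 to 718 ± 34.1 (log2 fold change -0.28, adjusted p = 0.00984) and then to 146 ± 3.03 (log2 fold change -2.29, adjusted p = 3.32e-07). The first of these steps no longer passed without day 11 replicate 1 (adjusted p = 0.0655) or without day 14 replicate 2 (adjusted p = 0.0631). VWF, which encodes von Willebrand factor, rose from 0.68 ± 0.15 to 6.81 ± 0.61 (adjusted p = 6.78e-06) and was at 5.2 ± 0.50 at day 24, a difference from day 14 that did not pass (log2 fold change -0.33, adjusted p = 0.0523). It did pass in 5 of the alternatives: with a pseudocount of 5 (adjusted p = 0.0247), without the trend (adjusted p = 0.0385), on the 4 libraries of these days alone (adjusted p = 0.0452), with the replicate number as a block (adjusted p = 0.0311) and with each library rescaled to a common total (log2 fold change -0.67, adjusted p = 0.00628).

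**Figure D2:**
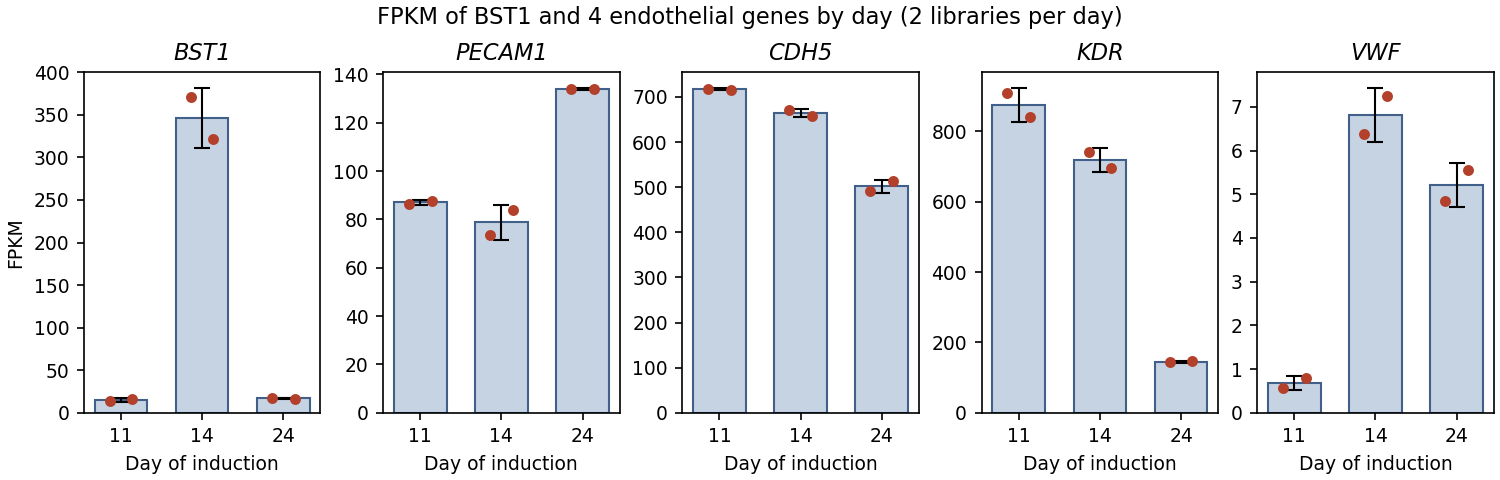
Bars give the mean FPKM of BST1, PECAM1, CDH5, KDR and VWF at days 11, 14 and 24, error bars the SD of 2 libraries and dots the single libraries, each panel on its own linear axis from 0. Both day 14 libraries of BST1 lie at 321 or above and the other 4 at 17.6 or below, while KDR is lowest at day 24.

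Between day 11 and day 14, genes of the cell cycle (24 of 28), of BMP and TGF-beta signalling (15 of 19) and of venous endothelium (8 of 10) rose, and genes of sprouting tip cells (14 of 20) fell. TAGLN, which encodes the actin-binding protein transgelin, rose from 3.36 ± 0.97 to 726 ± 158, and GJA5, the arterial gap junction gene for connexin 40, from 3.70 ± 0.27 to 526 ± 39.5. ANKRD1, which encodes an ankyrin repeat protein of striated muscle and of stretched cells, had the largest rise by the naming rule, from 0.15 ± 0.04 to 344 ± 34.6 (log2 fold change 8.23, SE 0.09, limma adjusted p = 6.75e-09). PGF, which encodes placental growth factor, fell from 122 ± 12.4 to 3.91 ± 0.14. Of the 12861 genes tested, 6993 changed: 3614 were higher and 3379 lower at day 14. A change of at least 2-fold was found for 1966 genes, 1041 higher and 925 lower.

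The other genes with the largest rises were TMEM100, a membrane protein gene of arterial endothelium (1.18 to 465), the imprinted noncoding RNA H19 (0.08 to 231), PALMD (0.09 to 224), RARRES2, which encodes the chemoattractant chemerin (0.19 to 239), TM4SF1 (0.28 to 225) and ANXA1, which encodes annexin A1 (0.36 to 228). CRABP1, a retinoic acid binding protein gene, was listed at 0 in both day 11 libraries and stood at 77.6 at day 14. The log2 rises of the 9 genes above 0 at day 11, TAGLN, GJA5 and ANKRD1 included, ran from 6.81 to 8.23. The largest falls after NOS2, the inducible nitric oxide synthase gene (50.5 ± 6.50 to 0.28 ± 0.15, log2 fold change -5.33, SE 0.14, adjusted p = 2.14e-07), were those of PGF, OIT3 (72.5 to 2.24), QPCT (39.7 to 0.77), CBLN1 (164 to 6.38), the fractalkine receptor CX3CR1 (22 to 0.09), the potassium channel KCNA5 (67.3 to 2.57), the transcriptional repressor PRDM1 (154 to 7.46) and KLHDC8A (20.2 to 0.20). ABCA9-AS1 also fell, from 46.1 to 0.77, but it is an antisense gene and the strand setting of the counting is not given in the sources used here, so its value is uncertain.

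Of the 39 gene lists that could be tested, 11 changed with the preset inter-gene correlation, 9 up and 2 down, and none of the 11 passed with an estimated correlation. The second setting also leaves the test 3 degrees of freedom, so a lost call does not show that correlation between members had made it. Counts of members are over all genes tested, and the counts adjusted over the list alone were the same unless given. In the cell cycle list, 24 of 28 members rose and 1 fell (25 and 2 adjusted over the list alone). The mitotic genes CCNB2 (0.88 to 13.1), AURKB (0.92 to 12.5), UBE2C (3.65 to 29.5) and CDC20 (2.64 to 21.4) rose most. The list was up with adjusted p = 8.18e-08 (adjusted p = 0.489 with an estimated correlation). In the BMP and TGF-beta list, 15 of 19 members rose and 3 fell (adjusted p = 0.000233, and adjusted p = 0.489 with an estimated correlation). BMP6 rose from 0.22 to 67.0, the BMP target ID1 from 22.9 to 177 and BMPER from 0.25 to 9.01, and INHBA, which encodes an activin subunit, was listed at 0 at day 11 and reached 24.7. Of the 16 p53 targets, 12 rose and 0 fell (adjusted p = 0.000233, and adjusted p = 0.489 with an estimated correlation), led by the stress cytokine GDF15 (2.78 to 35.2) and the cell cycle inhibitor CDKN1A (20.5 to 78.0).

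Venous, inflammatory and secretory lists also rose at day 14. In the venous list, 8 of 10 members rose and 1 fell, with APLNR (1.45 to 19.8), NT5E (6.48 to 49.8), IL1R1 (0.32 to 7.95) and the selectin gene SELE (1.27 to 11.5) in front (adjusted p = 0.000327, and adjusted p = 0.453 with an estimated correlation). This call ended over genes with mean FPKM of at least 5 (adjusted p = 0.0554). In the endothelial activation and NF-kB list, 10 of 14 rose and 1 fell (adjusted p = 0.00731, and adjusted p = 0.453 with an estimated correlation), among them the chemokine genes CXCL1 (0.44 to 17.6), CCL2 (0.29 to 12.6) and CXCL2 (1.18 to 18). The senescence and secretory list, which shares CXCL1 and CCL2 with it, had 10 of 16 members up and 3 down (adjusted p = 0.0109, and adjusted p = 0.453 with an estimated correlation), and IGFBP7 rose from 0.06 to 57.6. Of 13 imprinted and fetal growth genes, 8 rose and 2 fell (9 and 2 adjusted over the list alone), with IGF2 (1.39 to 31.2), PEG10 (0.34 to 15.0) and SNRPN (1.68 to 11.1) beside H19 (adjusted p = 0.0148, and adjusted p = 0.453 with an estimated correlation). The interferon list (6 of 9 up, 1 down) and the unfolded protein and amino acid list (9 of 16 up, 3 down) passed narrowly, both with adjusted p = 0.0467 and with adjusted p = 0.453 with an estimated correlation. ISG15 rose from 11.2 to 34.3 in the interferon list, and SLC7A11 (1.95 to 45.3), PSAT1 (9.21 to 86.8) and ASNS (6.97 to 44.6), genes of amino acid supply, led the other. Beside the estimated correlation, the interferon call ended in 9 of the 14 other settings that could be computed and the amino acid call in 7 of 15. These settings included leaving out either day 11 library (adjusted p = 0.0703 and adjusted p = 0.0543) or either day 24 library (adjusted p = 0.0647 for each) for the interferon list. For the amino acid list they included leaving out day 14 replicate 2 (adjusted p = 0.0834) or either day 24 library (adjusted p = 0.0647 for each).

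The 2 lists that fell were tip cell and sprouting genes and cholesterol biosynthesis. Of 20 tip cell genes, 14 fell and 2 rose (14 and 3 adjusted over the list alone), and the endothelial tip cell marker ESM1 fell from 2254 ± 144 to 226 ± 44.3. LXN fell from 564 to 39.3 and the laminin gene LAMA4 from 220 to 29.9 (adjusted p = 0.000132 for the list, and adjusted p = 0.453 with an estimated correlation). Of 18 cholesterol genes, 10 fell and 1 rose (12 and 1 adjusted over the list alone), including SQLE (201 to 90.2) (adjusted p = 0.0109, and adjusted p = 0.489 with an estimated correlation). Endothelial identity went both ways. Of 32 pan-endothelial genes, 14 rose and 11 fell, and the list did not pass (adjusted p = 0.478). CLEC14A rose from 1.71 to 76.3, TEK, the angiopoietin receptor gene, from 21.2 to 145, and MMRN1 from 53.3 to 219. The arterial list was likewise mixed (10 of 19 up, 5 down, adjusted p = 0.367), with JAG1 rising from 5.23 to 69.9 and HEY1, a Notch target, falling from 360 to 103. In other lists that did not pass, VEGFC (0.11 to 46.4), the endothelin gene EDN1 (4.61 to 162), fibronectin FN1 (8.0 to 488), the matricellular genes CYR61 (4.45 to 169) and CTGF (25.4 to 241) and lipoprotein lipase LPL (13.2 to 447) rose, and the lymphatic VEGF receptor gene FLT4 fell from 132 to 27.5.

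Between day 14 and day 24, genes of the cell cycle (28 of 28) and of the senescence and secretory list (13 of 16) rose, and arterial (16 of 19), pan-endothelial (23 of 32) and cholesterol genes (15 of 18) fell. The metallothionein gene MT2A rose from 9.94 ± 0.48 to 2170 ± 113 (log2 fold change 7.63, SE 0.21, limma adjusted p = 2.69e-07). The arterial gap junction gene GJA4 fell from 953 to 41.3 and NOS3, the endothelial nitric oxide synthase gene, from 42.7 to 1.0. Of the 12861 genes, 8012 changed, 4280 higher and 3732 lower at day 24, and 2294 changed at least 2-fold, 1131 higher and 1163 lower. The split of directions depended on scaling. With each library rescaled to a common total, the median log2 fold change of all genes moved from 0.02 to -0.28, and 2431 genes were higher and 6050 lower.

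The largest rise was that of HHIP, which encodes a Hedgehog-binding protein (0.29 ± 0.01 to 375 ± 8.90, log2 fold change 8.19, SE 0.09, adjusted p = 1.35e-08). KRT7, an epithelial keratin gene, was listed at 0 in all 4 libraries of days 11 and 14 and stood at 240 ± 24.8 at day 24. The protease gene MMP10 (0.10 to 107), the matrix genes LTBP2 (1.65 to 183) and EFEMP1 (10.1 to 668) and the cyclin gene CCNA1 (0.82 to 118) followed. The metallothionein genes MT1E (0.16 to 121) and MT1L (listed at 0 at day 14, 63.6 at day 24) also rose, but members of this family are similar in sequence and reads could be split between them. Genes with the largest falls included RARRES2 (239 to 0.11) and H19 (231 to 0.15), which had been near 0 at day 11, and COL15A1, a basement membrane collagen gene (808 ± 100 to 8.88 ± 0.06, log2 fold change -6.35, SE 0.10, adjusted p = 3.29e-08). PRND fell from 491 to 4.46, the natriuretic peptide clearance receptor gene NPR3 from 164 to 0.83, the cytochrome P450 gene CYP1B1 from 110 to 0.34, ENPP2, which encodes autotaxin, from 52.4 to 0.06 and IGDCC3 from 41.2 to 0.11. The neuropeptide gene CARTPT (108 at day 14) and the adenosine receptor gene ADORA2A (34.1 at day 14) were listed at 0 in both day 24 libraries.

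Of the 39 lists, 10 changed, 5 up and 5 down, and none of the 10 passed with an estimated correlation. As before, counts adjusted over the list alone were the same unless given. All 28 cell cycle genes rose, with RRM2 (14 to 70.3), MCM4 (11.4 to 37.0), TPX2 (13.9 to 43.0) and MCM7 (23.4 to 69.0) in front (adjusted p = 9.91e-08, and adjusted p = 0.447 with an estimated correlation). After rescaling to a common total, 23 of the 28 rose and 0 fell. Of 16 senescence and secretory genes, 13 rose and 3 fell (adjusted p = 0.000518, and adjusted p = 0.447 with an estimated correlation). CXCL8, which encodes interleukin-8, rose from 0.99 to 76.5 and IGFBP3 fell from 1184 to 58.6. Of 24 oxidative phosphorylation genes, 21 rose and 0 fell (adjusted p = 0.000518, and adjusted p = 0.447 with an estimated correlation), by small amounts such as SDHB (34.9 to 67.7) and COX7B (123 to 227). After rescaling to a common total 7 of these 24 rose, and after quantile normalization 10. In glycolysis, 16 of 20 rose and 2 fell (adjusted p = 0.00194, and adjusted p = 0.447 with an estimated correlation), with LDHA up from 57.9 to 224, PKM from 231 to 583 and the glucose transporter gene SLC2A3 down from 119 to 8.41. Rescaled, 12 rose and 3 fell. Of 16 p53 targets, 13 rose and 0 fell (adjusted p = 0.00482, and adjusted p = 0.608 with an estimated correlation), CDKN1A from 78.0 to 382 and GDF15 from 35.2 to 165. Rescaled, 10 rose and 2 fell.

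The lists that fell included arterial, pan-endothelial and junction genes. In the arterial list, 16 of 19 members fell and 1 rose (adjusted p = 9.39e-06, and adjusted p = 0.447 with an estimated correlation), GJA5 from 526 to 36.7 and UNC5B from 161 to 10.9. Of 32 pan-endothelial genes, 23 fell and 6 rose (24 and 6 adjusted over the list alone), including LMO2 (133 to 18.2), CYYR1 (67.6 to 8.73) and the tight junction gene CLDN5 (134 to 21.5) (adjusted p = 0.000518, and adjusted p = 0.447 with an estimated correlation). In the junction and barrier list, which shares GJA4, GJA5 and CLDN5 with these, 12 of 15 fell and 3 rose (adjusted p = 0.00600, and adjusted p = 0.447 with an estimated correlation). In the Notch list, 10 of 14 fell and 2 rose, DLL1 from 20.3 to 0.63 and HEY1 from 103 to 8.41 (adjusted p = 0.0148, and adjusted p = 0.575 with an estimated correlation). Both the junction call (adjusted p = 0.0568) and the Notch call (adjusted p = 0.0917) ended on the rescaled values, although their medians lay further below 0. Of 18 cholesterol genes, 15 fell and 1 rose (16 and 1 adjusted over the list alone), HMGCS1 from 44.5 to 6.61 and SQLE from 90.2 to 30.3 (adjusted p = 3.56e-05, and adjusted p = 0.447 with an estimated correlation). The tip cell list went both ways, with 9 of 20 up and 9 down (adjusted p = 0.982). PGF rose to 217 and the urokinase receptor gene PLAUR from 4.09 to 90.8, while the basement membrane gene NID2 fell from 71.3 to 3.65. Among progenitor markers, ABCG2 (22.1 to 0.28) and CD34 (572 to 120) fell with BST1, and 4 of 7 in that list fell and 2 rose (adjusted p = 0.175). ANGPT2, which encodes a ligand of TEK, rose from 24.1 to 197, and the protease inhibitor gene A2M fell from 157 to 4.10.

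Across the whole interval, from day 11 to day 24, genes of the cell cycle (27 of 28), of the senescence and secretory list (14 of 16) and of the p53 target list (15 of 16) rose, and cholesterol (16 of 18) and arterial genes (14 of 19) fell. ANKRD1 rose from 0.15 ± 0.04 to 1328 ± 85.3 (log2 fold change 10.17, SE 0.09, limma adjusted p = 2.79e-09) and FN1, which encodes fibronectin, from 8.0 ± 1.75 to 3321 ± 424. CD24, a surface glycoprotein gene of immature cells, fell from 419 ± 15.1 to 1.25 ± 0.16 (log2 fold change -7.55, SE 0.14, adjusted p = 2.07e-08). Of the 12861 genes, 9432 changed, 4920 higher and 4512 lower, and 3609 changed at least 2-fold, 1906 higher and 1703 lower. On the values rescaled to a common total, where the median log2 fold change of all genes was -0.31 instead of 0.03, 3223 were higher and 6360 lower.

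MT2A (1.0 to 2170), EFEMP1 (0.11 to 668), IGFBP7 (0.06 to 336), TM4SF1 (0.28 to 344), the protease inhibitor gene TFPI2 (0.39 to 358), THBS1, which encodes thrombospondin 1 (5.93 to 1617), and KRT7 were also among the 10 largest rises. With ANKRD1 and FN1, the log2 fold changes of those above 0 at day 11 ran from 7.87 to 10.17. CBLN1 (164 to 0.04), the chemokine scavenger receptor gene ACKR3 (130 to 0.67), the prostaglandin-degrading enzyme gene HPGD (72.0 to 0.02), OIT3 (72.5 to 0.03), KCNA5 (67.3 to 0.06), TNFSF10, which encodes the death ligand TRAIL (134 to 1.29), the lectin gene FCN3 (67.4 to 0.19) and PRND (271 to 4.46) fell by 5.74 to 7.31 on the log2 scale, and ADORA2A, at 78.6 at day 11, was listed at 0 in both day 24 libraries.

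Of the 39 lists, 10 changed, 6 up and 4 down, and none of the 10 passed with an estimated correlation. Counts adjusted over the list alone were the same as those over all genes in these 10 lists. The cell cycle list had 27 of 28 members up and 1 down (adjusted p = 4.61e-09, and adjusted p = 0.552 with an estimated correlation), RRM2 from 1.67 to 70.3 and UBE2C from 3.65 to 73.1. Of 16 p53 targets, 15 rose and 0 fell (adjusted p = 0.000159, and adjusted p = 0.552 with an estimated correlation), with CDKN1A going from 20.5 to 382. The senescence and secretory list had 14 of 16 up and 2 down (adjusted p = 0.000322, and adjusted p = 0.552 with an estimated correlation). MMP10 was listed at 0 at day 11 and reached 107, and CXCL8 went from 0.07 to 76.5. Of 24 oxidative phosphorylation genes, 23 rose and 0 fell (adjusted p = 0.000283, and adjusted p = 0.552 with an estimated correlation), 9 of them on the rescaled values. Glycolysis had 17 of 20 up and 1 down (adjusted p = 0.000836, and adjusted p = 0.552 with an estimated correlation), with 13 up and 3 down on the rescaled values. The BMP and TGF-beta list had 12 of 19 up and 3 down (adjusted p = 0.0280, and adjusted p = 0.608 with an estimated correlation), with BMP6 going from 0.22 to 95.1, BMP2 from 1.17 to 17.7 and TGFB2 from 0.24 to 9.35. That call ended over genes with mean FPKM of at least 5 (adjusted p = 0.122).

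Of the lists that were lower at day 24 than at day 11, cholesterol biosynthesis had 16 of 18 members down and 0 up (adjusted p = 1.33e-05, and adjusted p = 0.552 with an estimated correlation), with HMGCS1 going from 80.0 to 6.61 and SQLE from 201 to 30.3. The arterial list had 14 of 19 down and 4 up (adjusted p = 0.00882, and adjusted p = 0.552 with an estimated correlation), with HEY1 from 360 to 8.41 and GJA4 from 453 to 41.3, against JAG1 from 5.23 to 72.2. The tip cell list had 14 of 20 down and 6 up (adjusted p = 0.0283, and adjusted p = 0.552 with an estimated correlation), NID2 from 178 to 3.65 and TP53I11 from 307 to 22.3, against the apelin gene APLN from 41.5 to 662. The pan-endothelial list had 21 of 32 down and 9 up (adjusted p = 0.0429, and adjusted p = 0.608 with an estimated correlation), NOS3 from 40.3 to 1.0 and LMO2 from 146 to 18.2. On the rescaled values the arterial (adjusted p = 0.0865), tip cell (adjusted p = 0.210) and pan-endothelial (adjusted p = 0.188) calls ended, with medians further below 0 than on the deposited scale. The pan-endothelial call ended in 6 of the 15 other settings, among them without either day 14 library (adjusted p = 0.0589 for each) and without day 24 replicate 1 (adjusted p = 0.0541). In lists that did not pass, FLT4 fell from 132 to 2.26, THY1 from 295 to 5.61 and the secreted WNT inhibitor SFRP1 from 44.1 to 1.06. Also in such lists, the fatty acid binding gene FABP4 (0.67 to 68.3), EDN1 (4.61 to 453), CTGF (25.4 to 2068) and B2M, which encodes the light chain of class I HLA (91.6 to 679), rose.

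**Figure D3:**
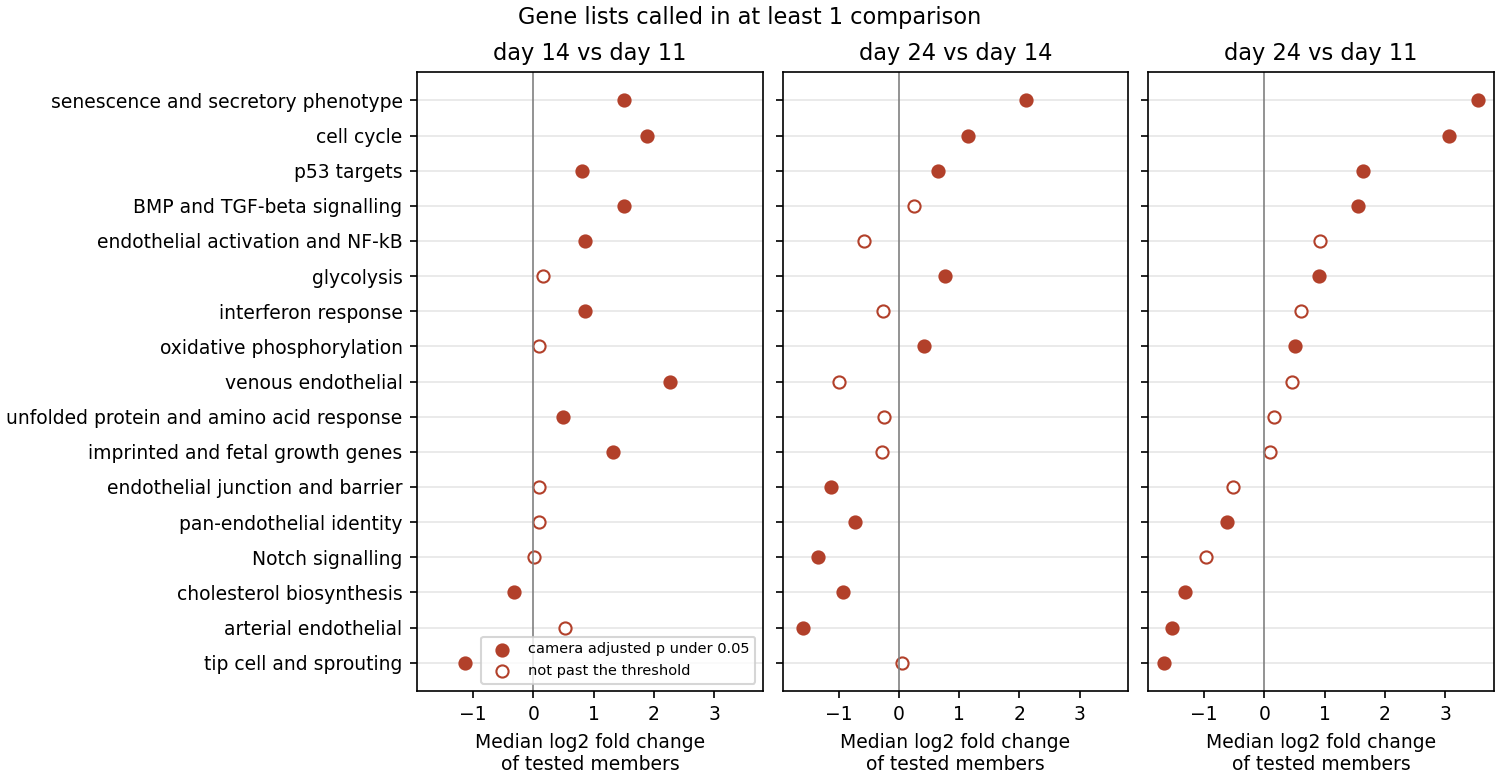
Each row is a gene list called in at least 1 of the 3 comparisons, the horizontal axis gives the median log2 fold change of its tested members, and filled points mark limma camera adjusted p under 0.05 with the preset correlation. The cell cycle list lies at 1.88, 1.14 and 3.05 in the 3 panels, and the cholesterol list lies below 0 in each, at -0.31, -0.93 and -1.31.

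The filter on low values was passed by 12861 of the 26255 genes in the table. Of the markers of other cell types, it was passed by 3 of 19 hemogenic and hematopoietic genes, 5 of 13 monocyte, 7 of 18 mural and smooth muscle, 7 of 18 fibroblast, 6 of 16 cardiomyocyte, 6 of 13 epithelial, 4 of 12 neural and 2 of 13 endoderm and hepatic genes. Lists with under 5 such genes were not tested as lists, and of the others none passed in any of the 3 comparisons. Without day 14 replicate 1 the cardiomyocyte list was up at day 14 (adjusted p = 0.0415) and down from day 14 to day 24 (adjusted p = 0.00816), and with no filter on low values it was down from day 14 to day 24 as well (adjusted p = 0.0392). The epithelial list was up from day 14 to day 24 without day 14 replicate 2 (adjusted p = 0.0269) and on the rescaled values (adjusted p = 0.0270). In the mural and smooth muscle list, MYL9 (17.9, 736 and 470 at days 11, 14 and 24), CNN1 (0.18, 9.80 and 22.5) and TAGLN (3.36, 726 and 925) were higher at both later days than at day 11, while 4 of the 7 tested members rose and 0 fell between days 11 and 24 (adjusted p = 0.169 for the list). On the rescaled values 3 rose and 2 fell, and the list's median log2 fold change turned from 0.22 to -0.14. The following single values were chosen after they were seen. PDGFRB and MYH11 in the same list reached at most 0.282 in any library. RGS5, also in that list, was at 92.3, 20.6 and 107 at days 11, 14 and 24. Of the fibroblast genes COL1A1 reached at most 0.379 and DCN 0.198, and LUM was listed at 0. COL3A1 rose to 5.91 at day 24. RUNX1, a transcription factor of hemogenic endothelium, rose from 1.77 to 23.9 between days 14 and 24, while the leukocyte genes PTPRC and SPI1 reached at most 0.0743 and 0.174. The lysosomal gene LAPTM5 was at 34.3, 10.5 and 131, and NKX2-5, a transcription factor gene of heart and some endothelium, at 0.73, 30.0 and 23.4. The adhesion molecule gene NCAM1 was at 0.05, 14.2 and 4.52. Besides KRT7, the epithelial genes KRT8 (17.1, 13.3 and 35.9) and CLDN6 (0.32, 1.25 and 9.45) were highest at day 24, but KRT18 (173, 67.3 and 123) and CLDN7 (50.2, 8.25 and 7.68) were highest at day 11. From day 11 to day 24, 3 of the 6 tested epithelial genes rose and 2 fell (adjusted p = 0.663 for the list), and 3 rose and 3 fell on the rescaled values. EPCAM reached at most 0.852 and CDH1 was listed at 0. The liver gene AFP was listed at 0 and ALB reached at most 0.0559. In the pluripotency list, which did not pass at day 24 against day 11 (2 of 9 up, 7 down, adjusted p = 0.0675), TDGF1 fell from 16.7 to 1.77 and 0.29 and DPPA4 from 26.1 to 5.34 and 2.39. POU5F1 was at 8.78, 7.33 and 23.7, but it shares sequence with several pseudogenes, and NANOG and SOX2 reached at most 0.185 and 0.687. Of the HOX genes, 8 of 28 were tested, including HOXB4 (4.49, 7.37 and 14) and HOXB6 (8.83, 16.3 and 14.1), while the 5 HOXC genes of the list were listed at 0. The lymphatic genes PROX1, LYVE1 and PDPN reached at most 0.622, 0.994 and 0.0451.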

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

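All alternatives below were chosen before the data were examined. No result named in the text reversed a call in any of them. Most counts stayed within 1.5 times those reported, with these exceptions. Genes changed at least 2-fold fell to 950, 1133 and 1952 (day 14 against 11, day 24 against 14, day 24 against 11) with a pseudocount of 5, which shrinks the changes of low genes, and to 1493 for day 24 against 14 with mean FPKM of at least 5, which leaves fewer genes to test. The lists changed fell from 11, 10 and 10 to 0, 0 and 0 with an estimated inter-gene correlation. That setting also cut the degrees of freedom of the list test to 3. The venous list at day 14 ended in it with an estimated correlation of -0.088, so correlation between members does not explain every lost call.

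BST1 kept both steps in every alternative. Its difference between days 24 and 11, which did not pass, ranged from 0.058 to 0.30 over the fits without 1 library and passed at 0.30 without day 11 replicate 2 (adjusted p = 0.0462, against adjusted p of 0.0462 to 0.652 over all alternatives). After rescaling to a common total its sign changed, to -0.18, again without passing. A fit without 1 library leaves its day with a single library, which is assumed to vary like the others.

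Of 434 calls on single genes named in the text, 406 were kept in every alternative and 28 ended in at least 1. Of 49 gene results not called, 28 were gained in at least 1. Of 31 calls on lists, rescaling to a common total ended 5 and added 4, and outside the estimated correlation 9 of the 31 ended in at least 1 alternative and 13 of the 86 list results not called were gained in at least 1. The values gave no sign that the numbers of libraries pair them across days: the deviations of replicate 1 from its day's mean correlated over genes by -0.10, 0.05 and -0.19 between days. A weak effect of shared cultures would not be seen in this check. With the replicate number as a block, 6978 (3599 higher), 7981 (4275 higher) and 9387 (4899 higher) genes changed, and the interferon and the amino acid list calls at day 14 ended (adjusted p = 0.0663 for each). Rescaling to a common total changed the split of directions against day 24, from 53.4% to 28.7% of called genes higher than at day 14 and from 52.2% to 33.6% higher than at day 11. The depth, known only as an estimate, limits genes of low FPKM most.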

Other observations

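All tests in this part except that of YAP and TAZ targets were chosen after the result was seen.

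For many genes day 14 was the highest or the lowest day. In both steps, 1119 genes were highest at day 14, 354 of them by at least 2-fold and 34 by at least 8-fold, where 1049, 94.1 and 1.03 would be met if the calls of the steps were independent. The lowest day was day 14 for 973 genes, 162 of them by at least 2-fold and 2 by at least 8-fold, against 1124, 81.3 and 0.365. The day 14 libraries enter both steps, so their own deviations add to such counts, by an amount that was not measured. The numbers for independent steps also take every gene as equally likely to change. Genes that vary more than others raise the counts at 2-fold and 8-fold in either direction, so an excess there does not by itself show a surplus at day 14. Among the genes highest at day 14, named after their values were seen, were LPL (13.2, 447 and 29.1 at days 11, 14 and 24), the collagen gene COL11A1 (2.14, 140 and 9.68), GPX3 (1.96, 74.0 and 1.74), PDLIM1 (4.03, 83.2 and 4.09), TSPAN7 (1.86, 58.8 and 0.88), PPP1R14A (0.11, 37.9 and 0.93) and CDH20 (0.26, 28.8 and 0.23). The alarmin gene IL33 was listed at 0 at day 11, stood at 18.3 at day 14 and fell to 0.03. The genes lowest at day 14 included PGF (122, 3.91 and 217), LAMA4 (220, 29.9 and 140), S100A13 (236, 41.3 and 232), OCIAD2 (51.0, 8.04 and 248), the proton-sensing receptor gene GPR4 (75.8, 10.5 and 61.0), ARHGAP18 (113, 7.21 and 34.5), RGCC (17.5, 2.49 and 44.3), the oxidase gene NOX4 (19.9, 4.06 and 47.7) and TGFBI (4.32, 0.06 and 8.49).

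BST1 was highest at day 14. Neither library scaling nor a single library accounts for it, since the log2 rise from day 11 was 4.45 or more after either rescaling and at least 4.32 without any 1 of the 6 libraries. Cells picked for CD157 at day 14 only remain open: such a sort would act on BST1 directly, and BST1 ranked 12 among the 1119 genes highest at day 14, behind genes such as H19, RARRES2 and CYP1B1. The labels name no sort, and no value here decides. A change of cell state by day 14 is the biological alternative, and the design does not test it apart from a sort.

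Genes beside BST1 also peaked at day 14. Its 6 nearest tested neighbours, CPEB2 (5.58, 10.5 and 4.21), CC2D2A (6.45, 11 and 6.32), FBXL5 (19.4, 61.2 and 16.1), FAM200B (5.16, 11.4 and 5.08), TAPT1 (2.43, 4.02 and 2.49) and LDB2 (127, 174 and 28.9), passed both steps, although TAPT1 no longer did without day 11 replicate 1 (adjusted p = 0.0543 for the first step), day 14 replicate 2 (adjusted p = 0.0522 and adjusted p = 0.0528) or day 24 replicate 1 (adjusted p = 0.0654 for the second), nor LDB2 in the first step without day 11 replicate 2 (adjusted p = 0.0545) or day 14 replicate 2 (adjusted p = 0.0761). Gain of the whole of chromosome 4 would raise its 456 tested genes, whose median log2 fold change was 0.057, and reads running on past the 3' end of BST1 would miss the upstream FBXL5, which changed by at least 1.61 in both steps. Chance placement is rare, as the neighbours' median was as high for 0.277% of 12653 tested genes, and CD38, the related gene next to BST1, was too low to test, at 0 and 0.08 at day 11, 0.73 and 1.23 at day 14 and 0.07 and 0 at day 24. A regional change of chromatin at day 14 may explain the shared peak, as a hypothesis that expression values do not test, and a gain of part of the chromosome by some of the day 14 cells was not tested.

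Some contractile and matrix genes, TAGLN, CNN1, FN1 and THBS1 among them, rose by day 24, although the lists of mural and smooth muscle (4 of 7 up, 0 down, adjusted p = 0.169, or 3 up and 2 down after rescaling to a common total, with a median that turned to -0.14), matrix remodelling (11 of 19 up, 8 down, adjusted p = 0.237) and basement membrane genes (10 of 17 up, 7 down, adjusted p = 0.663, or 8 up and 7 down rescaled) did not pass. Admixed fibroblast or mural cells would bring abundant collagens, but the highest of COL1A1 (0.31), COL1A2 (1.33) and COL3A1 (5.91) at day 24 was 0.642% of the TAGLN rise of 921. RGS5 of the mural list was at 92.3, 20.6 and 107 at days 11, 14 and 24. It fell between days 11 and 14 while TAGLN rose from 3.36 to 726, so it did not follow the contractile rise. PDGFRB and MYH11 of that list stayed low in every library, as given above. These single genes were picked after their values were seen, and with the collagens they do not exclude mural cells. A candidate explanation is a YAP and TAZ target programme, the response of cells to stretch and stiff surfaces. The median log2 fold change of the 14 of its 22 listed targets whose values had not been looked at was 1.15, at percentile 99.98 of 10000 random lists matched on expression (their median 0.04, 95th percentile 0.48). The genes of the random lists were drawn independently, so the percentile takes no account of correlation among the targets and can overstate the difference. Of these 14, 10 rose, 2 fell and 2 did not pass, led by AXL (6.07), MYOF (4.0) and AMOTL2 (3.48), and as other programmes share these targets this remains a hypothesis.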
